A study of Mus musculus with 8 samples.

How the data were processed

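Total RNA from the livers of 8 male mice (4 wild type, 4 Bgn knockout, aged 13 weeks) was extracted with a column kit, checked on a Bioanalyser, labelled with biotin and measured on Illumina bead arrays, per the labels' protocols. Each sample was taken from its label, and each column was matched to a sample through that sample's description. The deposited table without normalization holds, per the file headers, an average intensity and a detection p-value for each probe on each array. Its intensity values are linear, were not subtracted for background (lowest value 109) and were not normalized between arrays, as their differing distributions show. How the detection p-value was made is not given in the sources used here. A second deposited table holds the authors' normalized intensity on a linear scale. In it, the column of wild type replicate 4 equals its unnormalized column, and each other column keeps the rank order of its own unnormalized values. Its column medians lay between 155.9 and 156.6, and the normalization method is not given in the sources used here. The submitters' processing notes name lumi 2.10.0 and R 2.15.0, without saying which step used them.

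The unnormalized intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc estimated the background mean and SD from the detection p-values, applied normexp correction with an offset of 16, quantile normalization and log2. A probe was tested if its detection p was under 0.05 on at least 4 of the 8 arrays, which left 11494 probes of 8105 genes. The platform table named 1 gene for 23978 of the 25697 probes, none for 1719 and several for 0, and 23962 Entrez numbers matched the reference table of assembly GRCm38.p6, with 0 symbols changed. That table was used only for names and for which genes neighbour each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

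Bgn knockout was compared with wild type in a linear model (lmFit, then eBayes with trend and robust variance), without covariates, and p-values were adjusted with Benjamini-Hochberg over all tested probes at a threshold of 0.05. A probe not detected on any array of a group has only a bound there: the fold is given as at least the bright group's mean over the mean, per array of the dim group, of the higher of the lowest detected signal and the probe's own value. A total of 48 gene lists of liver functions, cell types and location was tested, of which 43 had at least 5 measured genes, with camera at a preset correlation of 0.01 and the brightest tested probe of each gene. The test with an estimated correlation and fry were run beside it. With the estimated correlation 0 lists passed (smallest adjusted p = 0.768; 2 lists at an unadjusted p under 0.05), and with fry 0 passed in one direction (smallest adjusted p = 0.0711; 6 at an unadjusted p under 0.05) and 14 in either direction.

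Named genes are Bgn, the 12 genes with the largest rise and the 12 with the largest fall among changed probes with 1 gene symbol whose groups did not overlap, and from lists the changed members (up to 4) or up to 3 with the smallest p, said not to pass, with up to 4 more with the largest change for a list past its test. These rules, the lists, the tests and the alternatives were fixed before the data were examined, except where the text says otherwise. Other tested probes of a named gene are given where they disagree. Outside these rules, the relatives of Serpina1e and Cyp4a12b and the genes named by their chromosomal neighbours were added later, after their values were seen. Socs2 and Igf1 were chosen after the values of Cish, Bcl6 and the growth hormone list's median, but before their own values were seen.

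The fit was tested on simulated data for this comparison with 11494 probes. At a log2 change of 0.5, 12 of 67 changed probes were recovered (17.9%), at 1 it was 50 of 67 (74.6%) and at 2 it was 61 of 66 (92.4%), and 8 of 131 calls were false (6.11%). The simulated noise was independent between probes. On the real arrays genes can vary together, with an estimated correlation of 0.81 for cholesterol synthesis, so these rates may not hold there. Alternatives were no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' normalized values, no filter, a filter of detection p under 0.01 on all arrays, eBayes without trend and robust variance, array weights, the replicate number as a block, another summary of probes per gene, and leaving out each array in turn. A chip as a block could not be fitted, since the columns name no chips.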

Results

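Whole-liver RNA was measured on single-colour Illumina bead arrays in 8 male mice aged 13 weeks, 4 wild type and 4 carrying a knockout of Bgn, the gene for the matrix proteoglycan biglycan. Each mouse gave 1 array, and the labels place all mice on a C57BL/6 background. The median deposited signal lay between 141 and 164 intensity units per array, and 11352 to 11910 of the 25697 probes were detected. The number of arrays limits the precision. The comparison asks how liver transcripts differ between the genotypes at this age.

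Bgn itself was reported first because it checks the labels. The deposited Bgn signal averaged 3660 ± 918 in wild type livers and 190 ± 15.3 in knockout livers (SD, n = 4 each), so the knockout signal was 5.19% of the wild type signal. After background correction the fall was 5.86 on the log2 scale (SE 0.14; 58.2-fold; limma, Benjamini-Hochberg adjusted p = 2.38e-10), and each knockout array lay below each wild type array (exact two-sided permutation p = 0.0286, the smallest the 70 label assignments allow). Without background correction the log2 change was -4.33. The probe stayed above background on the 4 knockout arrays. The part of the gene removed in the knockout is not given in the sources used here.

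**Figure D1:**
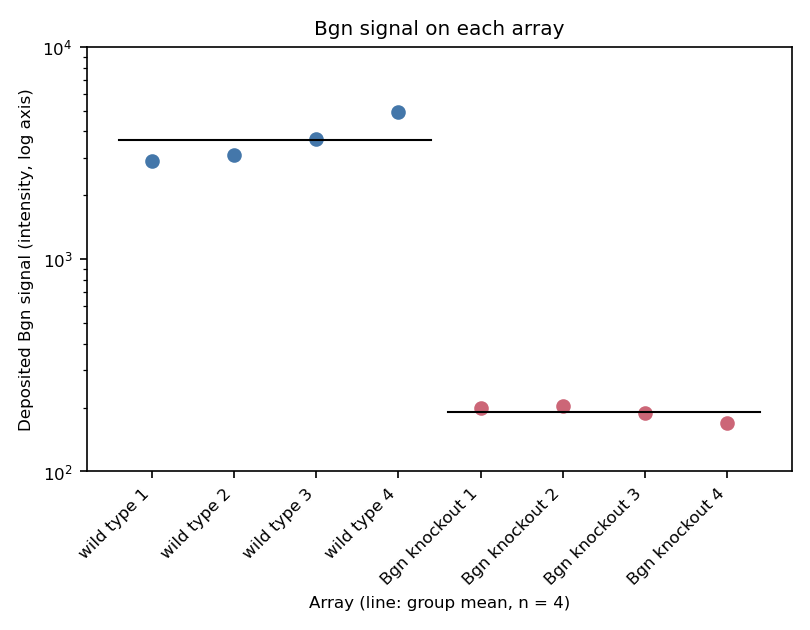
Deposited Bgn signal (intensity, log axis) on each of the 8 arrays, blue for wild type and red for Bgn knockout, with lines at the group means. The wild type arrays lie between 2901 and 4944, and the knockout arrays between 169 and 203.

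In knockout livers, Serpina1e, an alpha-1-antitrypsin gene, fell most after Bgn, and Dbp, a transcription factor of the clock's output, fell 11.6-fold. Ppp1r3b, which targets protein phosphatase to glycogen, rose 5.64-fold, the repressor Bcl6 rose 4.62-fold, and Apcs, which encodes serum amyloid P, rose 4.48-fold. Cyp17a1, a steroid hydroxylase, fell 6.61-fold, and Mrap, the accessory protein of the melanocortin receptor, fell 4.58-fold. The folds of Dbp and Ppp1r3b depend on the background correction, without which the log2 change was -2.81 in place of -3.53 for Dbp and 1.74 in place of 2.50 for Ppp1r3b. In all, 127 of 11494 tested probes changed, 44 higher and 83 lower in the knockout, from 112 named genes and 6 probes without a gene name (limma, Benjamini-Hochberg adjusted p under 0.05). Of the 112 genes, 34 had several tested probes. All probes passed for 4 of these genes, and all had the same sign for 27. Of the 127 probes, 82 changed more than 2-fold, a count that rests on the background correction. Without it, rises such as that of Itga9 (log2 change 0.50) stay below 2-fold. The 2 groups did not overlap for any of the 127, and over all tested probes they did not overlap for 8.07%, against 2.86% by chance.

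Among the 12 largest rises, Ppp1r3b rose by 2.50 (SE 0.44) on the log2 scale, Serpina11 by 2.47 (SE 0.14), Bcl6 by 2.21 (SE 0.34), Apcs by 2.16 (SE 0.31) and Trmt9b by 1.66 (SE 0.22). Bik, a pro-apoptotic BH3-only gene, rose by 1.49 (SE 0.25), and so did Ttc39a (SE 0.22), detected on 2 of the 4 wild type arrays. On 1 of its 2 tested probes, Slc7a2, a cationic amino acid transporter, was not above background on any wild type array and was at least 4.39-fold higher in the knockout by background-corrected signal, while the second probe gave a log2 change of 0.42 (limma adjusted p = 0.152). Absence of detection in wild type also held for the integrin gene Itga9 (at least 2.06-fold), Vmn1r65 (at least 2.05-fold) and Mkx (at least 2.09-fold), where such bounds set the bright group against the lowest detected signal of the other arrays and rest on the background correction. Without that correction the log2 change was 0.93 for Slc7a2, 0.50 for Itga9, 0.60 for Vmn1r65 and 0.46 for Mkx, and it was 0.71 for Lcmt1, 0.74 for Trmt9b, 0.84 for Bik and 0.51 for Ttc39a, all past the threshold. Lcmt1 rose by 1.75 (SE 0.18) on 1 of its 3 tested probes, with changes of -0.14 and 0.05 on the others. Ppp1r3b, Trmt9b and Slc7a2 neighbour each other on chromosome 8 among the tested genes (assembly GRCm38.p6). Apcs lay within 5 tested genes of another changed gene, Ackr1, on chromosome 1. Leaving out 1 array ended the call of Ppp1r3b for 7 of the 8 arrays (limma adjusted p up to 0.131), of Bcl6 for 6 (up to 0.112) and of Apcs for 4 (up to 0.0711). On all 8 arrays, Ppp1r3b and Bcl6 did not pass with no filter on dim probes (limma adjusted p = 0.123 and 0.0851), nor did Apcs with array weights (0.0625). Leaving out 1 array ended the call of Bik without wild type replicate 1 or Bgn knockout replicate 2 (0.054 and 0.0722), of Mkx without wild type replicate 1 or 2 (0.0705 and 0.0552) and of Vmn1r65 without wild type replicate 1 (0.0505). Slc7a2, Itga9, Vmn1r65 and Mkx were not tested without a knockout array, since too few arrays then detected them.

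Among the 12 largest falls, the log2 change was -5.12 (SE 0.20) for Serpina1e, -3.53 (SE 0.20) for Dbp, -2.72 (SE 0.42) for Cyp17a1, -2.38 (SE 0.21) for the mitochondrial ribosomal gene Mrps27, -2.23 (SE 0.18) for Gpn2 and -2.20 (SE 0.11) for Mrap. Cibar1 fell 4.42-fold, and its second probe, with a log2 change of -1.94 (SE 0.20), passed as well. Without background correction the first had -1.47. Cxadr, the coxsackievirus and adenovirus receptor, fell by 4.18 (SE 0.22) on 1 probe, while its other probes gave 0.17 and 0.0042. Taf12, a subunit of the general transcription machinery, likewise fell by 3.06 (SE 0.18) on 1 probe, with -0.092 and 0.13 on the others, and the falling probe was detected on 3 of 4 knockout arrays. Tesk1 fell by 3.04 (SE 0.48) and was detected on 2 of 4 knockout arrays. Sytl1 and Zfp738 were not above background in the knockout and were at least 6.97-fold and 4.46-fold lower by background-corrected signal, and they were not tested without a wild type array. Without background correction the log2 change was -1.29 for Sytl1, -1.03 for Zfp738, -1.52 for Taf12, -1.52 for Tesk1, -1.26 for Mrps27, -1.57 for Gpn2 and -2.62 for Cxadr, all past the threshold. Leaving out 1 array ended the call of Tesk1 for 7 of the 8 arrays (limma adjusted p up to 0.0921) and of Cyp17a1 for 5 (up to 0.105). On all 8 arrays, neither passed with no filter on dim probes (limma adjusted p = 0.0755 and 0.086), nor did Tesk1 with array weights (0.0599). Sytl1, Gpn2, Tesk1 and Cibar1 each lay within 5 tested genes of another changed gene on chromosome 4 (assembly GRCm38.p6). The same held for Cyp17a1 on chromosome 19 and Zfp738 on chromosome 13. The probes without a gene name with the largest changes were ILMN_2970494 (5.36 higher, SE 0.16) and ILMN_2666279 (-3.91, SE 0.28, and -2.93 without background correction).

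**Figure D2:**
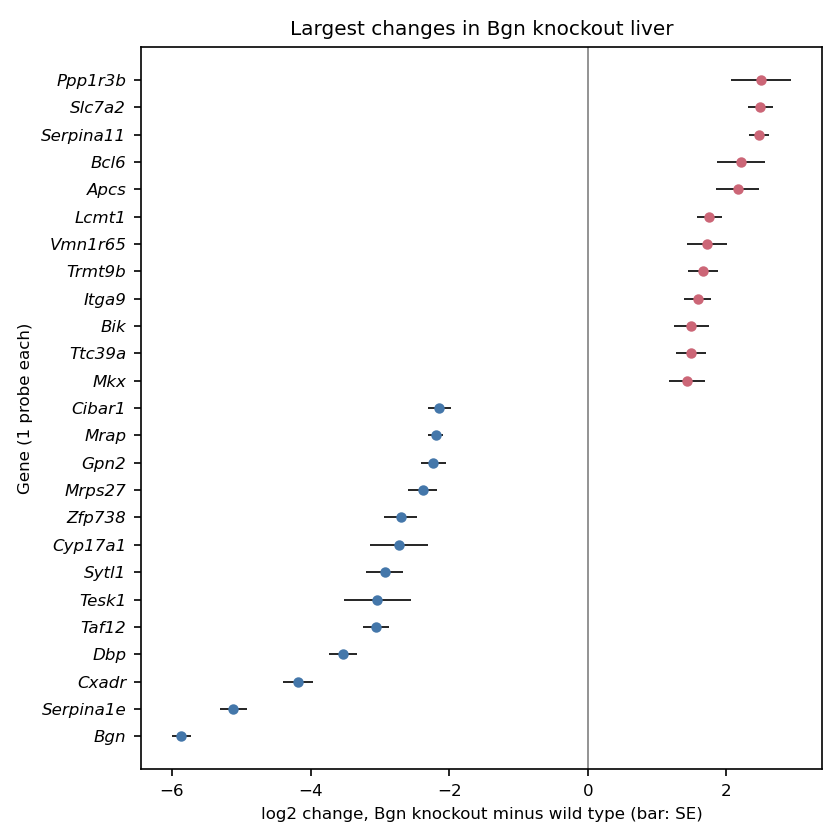
Log2 change (Bgn knockout minus wild type, 4 arrays each) of Bgn and the 12 genes with the largest rise and fall, 1 probe per gene, with bars for the SE. Changes run from -5.86 for Bgn to 2.50 for Ppp1r3b, and those of Slc7a2, Itga9, Vmn1r65, Mkx, Sytl1 and Zfp738, not detected in 1 group, are fitted values, not bounds.

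Clock genes formed the list with the most changed members. Of the 19 measured genes of the circadian clock and its output, 3 were lower and 1 was higher in the knockout, and 15 did not pass. Dbp, Tef (-1.31, SE 0.16), another transcription factor of the clock's output, and the repressor Nr1d1 (-1.66, SE 0.30) fell, and the activator Arntl rose by 0.96 (SE 0.19). Adjusted over the list alone, 7 genes were lower and 3 higher. Usp2 changed by -1.40 (SE 0.47) without passing (limma adjusted p = 0.267), and it passed without Bgn knockout replicate 4 (0.0125). The list's median log2 change was -0.31, and limma's camera with a preset correlation called it lower (adjusted p = 0.0103), but not with an estimated correlation (adjusted p = 0.768) or without wild type replicate 1 (adjusted p = 0.0538). Without Bgn knockout replicate 4 the median was -0.53. The labels give no hour of collection. The second Nr1d1 probe gave -1.27 (adjusted p = 0.282). Leaving out 1 array ended the call of Nr1d1 for 6 of the 8 arrays (limma adjusted p up to 0.0991) and of Arntl for 6 (up to 0.133), while Dbp and Tef passed without each array. On all 8 arrays, Nr1d1 did not pass with no filter on dim probes (limma adjusted p = 0.0531), nor Arntl with eBayes without trend and robust variance (0.0538), and without background correction Arntl had 0.61.

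**Figure D3:**
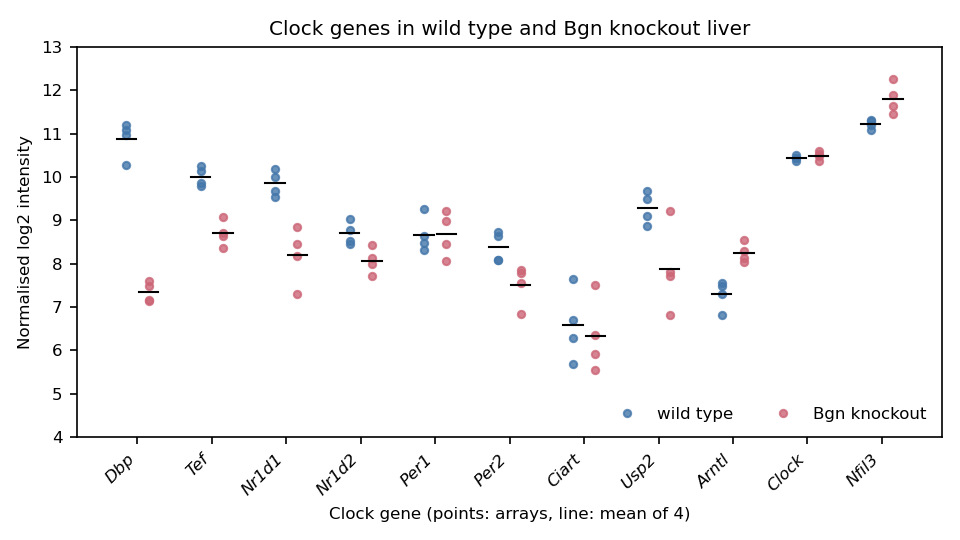
Normalised log2 intensity of 11 clock genes on each array (blue for wild type, red for Bgn knockout, line for the mean of 4 arrays). The 4 knockout arrays lie below the 4 wild type arrays for Dbp, Tef, Nr1d1, Nr1d2 and Per2 and above them for Arntl and Nfil3. Nr1d2, Per2 and Nfil3 did not pass in limma.

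The oxidative phosphorylation list was called higher by camera (adjusted p = 0.00968), but not with an estimated correlation (adjusted p = 0.768). Of its 53 measured genes 0 were past the threshold in limma, with 11 with values above 0 and none below 0 at an unadjusted p under 0.05, and 3 higher when adjusted over the list alone. Its median log2 change was 0.061, and it was -0.074 with median scaling, where the call was lost (adjusted p = 0.967). Cycs (0.85, SE 0.30), Cox7b (0.72, SE 0.17) and Atp5a1 (0.47, SE 0.12) had the largest values. Markers of Kupffer cells and macrophages were called lower by camera (median -0.21 over 14 genes; adjusted p = 0.042), but not with an estimated correlation (adjusted p = 0.933). In it, 0 genes were past the threshold in limma, 0 adjusted over the list alone and 5 lower at an unadjusted p under 0.05. Cd163 had -0.64 (SE 0.19), Cd14 -0.57 (SE 0.26) and Aif1 -0.52 (SE 0.22). Leaving out wild type replicate 2 or 4 or Bgn knockout replicate 2 or 3 ended the camera call (adjusted p = 0.0657, 0.24, 0.21 and 0.223). Per array, the list's median deviation was highest on wild type replicate 4 (0.47) and lowest on Bgn knockout replicate 2 (-0.48), which are also the arrays with the highest Tnnt3, a muscle gene, and without both camera gave an adjusted p of 0.674. The list's median log2 change was -0.13 without wild type replicate 4, -0.31 without Bgn knockout replicate 4 and -0.11 without background correction.

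Of the 48 lists, 10 held a gene whose brightest probe changed, and 12 held one with any changed probe, through Irf1 and Bcap31 below. Serpina1e and Cyp4a12b (-2.07, SE 0.28), of the male-biased liver genes, were lower and Bcl6 was higher, and the other 22 of 25 measured genes did not pass. The list's median was 0.16 and its mean -0.063, and median scaling turned the median to -0.013. It was 0.26, 0.31, 0.093 and 0.067 without wild type replicates 1 to 4 in turn. Their close relatives gave other values: Cyp4a12a had 0.45 (SE 0.16; limma adjusted p = 0.255), Serpina1c fell by 1.37 (SE 0.063), and Serpina1d had -0.069 (SE 0.056). Cyp17a1 was the changed gene among 14 measured female-biased genes. Apcs was the changed gene among 24 acute phase genes, Ppp1r3b among 14 genes of gluconeogenesis and glycogen, and Mogat1, a monoacylglycerol acyltransferase, rose by 1.23 (SE 0.25; detected on 1 of 4 wild type arrays) among 22 genes of fatty acid and triglyceride synthesis. Rps3a1 fell by 0.93 (SE 0.18) among 48 cytosolic ribosomal genes (Rpl23 had -0.84 on 1 of its 3 probes, limma adjusted p = 0.0294, and -0.043 and 0.027 on the others), and Anxa4 had a log2 change of -1.90 (SE 0.16) among 7 cholangiocyte markers. Leaving out 1 array ended the call of Mogat1 for 6 of the 8 arrays (limma adjusted p up to 0.151), of Rps3a1 for 5 (up to 0.117) and of Cyp4a12b without wild type replicate 3 (0.0561). On all 8 arrays, Mogat1 did not pass without background correction (log2 change 0.39, limma adjusted p = 0.0514), with a normexp offset of 50 (0.0535) or with eBayes without trend and robust variance (0.0573), nor Rps3a1 with the latter (0.0673), and without background correction Anxa4 had -1.19. In the growth hormone and IGF axis, 0 of 14 genes passed and 2 had an unadjusted p under 0.05 in limma, Cish with -3.15 (SE 0.61; adjusted p = 0.0814) and Socs3 with -1.27 (SE 0.46; adjusted p = 0.29). Cish passed in limma without wild type replicate 1 (adjusted p = 0.02) and with eBayes without trend and robust variance (0.0312), and adjusted over the list alone 1 gene was lower.

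Matrix genes related to biglycan did not pass as reported. Among 4 measured small leucine-rich proteoglycans, Lum had 0.72 (SE 0.19; limma adjusted p = 0.108) and Ogn 0.34 (SE 0.23). Adjusted over the list alone 1 gene was higher, and Lum passed in limma without wild type replicate 2 (adjusted p = 0.0493). Among 15 collagens and matrix proteins, 0 passed in limma and 0 had an unadjusted p under 0.05, with 0.40 (SE 0.19) for Col4a2 and 0.32 (SE 0.16) for Sparc. Of 28 interferon response genes, 24 had values below 0 and 0 of the probes used for the list passed in limma (5 at an unadjusted p under 0.05, 1 lower adjusted over the list alone; camera adjusted p = 0.0661). The interferon response list was called lower by camera with no filter on dim probes (adjusted p = 0.0397), without wild type replicate 2 (0.00626) and without Bgn knockout replicate 1 (0.00479), but not with an estimated correlation (0.933). Irf1 had values below 0 on all 4 of its probes, of which 1 passed (-1.06, SE 0.20, limma adjusted p = 0.0287). Its brightest probe had -0.85 (limma adjusted p = 0.0668), passing with median scaling (0.0414) and without Bgn knockout replicate 1 (0.0308). The remaining probes had -0.59 and -0.64 (limma adjusted p = 0.249 and 0.302). Of 29 measured neighbours of Bgn on the X chromosome, 1 had a changed probe, Bcap31, with 0.78 (SE 0.16) on that probe and 0.26 (SE 0.11) on its brighter one.

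Muscle transcripts differed between arrays within both groups. Tnnt3 had a log2 intensity of 11.03 on wild type replicate 4, 11.26 on Bgn knockout replicate 2 and 8.79 on Bgn knockout replicate 1, against 4.47 to 5.45 on the other arrays. Without wild type replicate 4 and Bgn knockout replicate 2, an alternative chosen after seeing the data, 48 probes passed, 41 of them among the 127.

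The number of changed probes fell by more than 1.5 times when single arrays were left out: to 62 without wild type replicate 1 (21 higher, 41 lower), 67 without wild type replicate 3 (22 higher, 45 lower), 81 without Bgn knockout replicate 1 (23 higher, 58 lower), 59 without Bgn knockout replicate 2 (14 higher, 45 lower) and 68 without Bgn knockout replicate 3 (13 higher, 55 lower). The share of higher probes, 34.6% as reported, was 19.1% without Bgn knockout replicate 3, and with array weights 197 probes passed (74 higher, 123 lower).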

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

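In groups of 4 arrays, 1 array was called far from the others where its gap to the nearest, divided by the group's range, exceeded Dixon's critical value. Chance alone gives about 1 in 20 groups. Of 392 groups checked, 28 met the rule, against 19.6 expected by chance.

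Among genes with the largest changes, Slc7a2 was 7.59 on Bgn knockout replicate 2 (others 7.19 to 7.20), and Apcs was 10.3 on Bgn knockout replicate 1 (others 11.65 to 11.67), all as log2 intensity. Cyp17a1 was 11.99 on wild type replicate 4 (others 10.25 to 10.37). On wild type replicate 2, Sytl1 was 7.06 (others 8.24 to 8.31) and Gpn2 was 8.86 (others 9.50 to 9.60).

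Among members of gene lists, the log2 intensity on wild type replicate 1 was 5.57 for Adamts5 (others 4.79 to 4.87), 7.44 for Ngfr (others 7.27 to 7.28) and 7.63 for S100a8 (others 6.30 to 6.46). On the other wild type arrays it was 12.65 for Krt8 on replicate 2 (others 12.11 to 12.21), 7.65 for Col4a2 on replicate 3 (others 8.17 to 8.24), 9.12 for Irs2 on replicate 4 (others 7.59 to 7.76) and 11.03 for Tnnt3 on replicate 4 (others 4.52 to 4.68). On Bgn knockout replicate 4 it was 5.92 for Cd14 (others 5.31 to 5.33), 8.13 for Dhcr7 (others 9.25 to 9.45), 11.62 for Pnpla2 (others 10.79 to 10.86) and 5.89 for Ddit3 (others 5.25 to 5.30). It was 6.75 for Rgs5 on Bgn knockout replicate 1 (others 8.06 to 8.19), 8.96 for Insig1 on Bgn knockout replicate 3 (others 8.09 to 8.12) and 13.15 for Hba-a1 on Bgn knockout replicate 3 (others 14.05 to 14.19).

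Per array, the median deviation of a list's genes from their means stood apart for erythroid markers on wild type replicate 1 (0.37) and Bgn knockout replicate 3 (-0.77), and for adipose and muscle markers on wild type replicate 4 (2.17). It also stood apart on Bgn knockout replicate 4 for the unfolded protein response (0.12), acute phase proteins (0.18) and neighbours of Bgn (0.073), on Bgn knockout replicate 2 for matrix remodelling enzymes (0.096) and on Bgn knockout replicate 1 for the cell cycle (-0.099). Wild type replicate 4 had 11910 detected probes, against 11423 to 11451 on the other wild type arrays.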

How the results depend on the processing

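The alternative without wild type replicate 4 and Bgn knockout replicate 2 was chosen after seeing the data. Bgn was lower and past the threshold in all 19 alternatives (log2 change -5.92 to -4.33). The 127 changed probes became 197 with array weights and 48 without wild type replicate 4 and Bgn knockout replicate 2 (8 higher, 40 lower), and 59 to 121 when each array was left out in turn; fewer arrays lower the power, and for the array weights the cause was not tested. In the other alternatives on all 8 arrays except the block, the count lay between 96 and 130. With the replicate number as a block, where Bik, Mkx, Tesk1, Mogat1, Arntl, Nr1d1 and Rps3a1 did not pass, 64 probes passed, 60 of them among the 127. The labels do not say what the numbers mark. Same-numbered arrays had correlations of -0.30 to 0.057 in their deviations, and 0 knockout arrays correlated best with their own number. These values show no sign of pairing but cannot exclude it.

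For the gene lists, 3 passed in the reported test, 0 with an estimated correlation, which tests against a wider spread, and 0 with fry, which does not compare a list with other genes. Leaving out each array in turn gave 2 to 4 lists. Median scaling gave 4, of which 2 were shared, with cytosolic ribosomal proteins and hepatocyte markers in place of oxidative phosphorylation. The interferon response list passed with no filter, with the block (adjusted p = 0.0459) and without wild type replicate 2 or Bgn knockout replicate 1, and erythroid markers passed without wild type replicate 4 and Bgn knockout replicate 2 (0.048). Kupffer cell markers also missed the threshold with the authors' normalized values (adjusted p = 0.0506), the stricter filter (0.0837), array weights (0.0628) and without wild type replicate 4 and Bgn knockout replicate 2 (0.674). Over the alternatives that kept the preset correlation, the adjusted p of that list lay between 0.00608 and 0.674, that of the clock list between 0.00116 and 0.0538 and that of oxidative phosphorylation between 0.00173 and 0.967.

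Without wild type replicate 4 and Bgn knockout replicate 2, the calls of Ppp1r3b, Bcl6, Apcs, Bik, Mogat1, Cyp4a12b, Arntl and Rps3a1 were lost (limma adjusted p 0.0794 to 0.311). Their directions held, and the values that moved most for their size were 0.95 for Mogat1 (1.23 reported), -0.74 for Rps3a1 (-0.93) and 1.27 for Bik (1.49). Fewer arrays lower the power, so these losses do not tie the changes to the muscle transcripts. Of 114 list members chosen by the rule that did not pass, 16 passed in 1 to 3 alternatives. Directions turned for 3 genes that did not pass, and the cause was not tested: with median scaling Errfi1 (0.14 reported) became -0.10 and Glo1 (0.091) became -0.12, and Cela2a (0.11) became -0.035 with array weights, -0.027 without wild type replicate 4 and Bgn knockout replicate 2, and -0.078 to 0.30 when single arrays were left out (-0.078 without wild type replicate 3 and -0.024 without Bgn knockout replicate 3). Probes near background limit what can be compared: Slc7a2, Itga9, Vmn1r65, Mkx, Sytl1 and Zfp738 have only bounds, which rest on the background correction. These 6 genes were not tested with the stricter filter, without wild type replicate 4 and Bgn knockout replicate 2, or without an array of the group that detects them.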

Other observations

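The tests on neighbouring genes and on the clock were chosen after the results were seen; that of Socs2 and Igf1 was written after Cish and Bcl6 but before their own values were seen, and that of other splits before its result.

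Genes of cholesterol synthesis differed between arrays within each group. Their median deviation was 0.75, 0.74, -0.89 and -0.61 on wild type replicates 1 to 4 and 0.48, 0.0069, 0.23 and -0.86 on Bgn knockout replicates 1 to 4, and 0 of 18 genes differed between the genotypes in limma (0 at an unadjusted p under 0.05). Among the stellate cell and fibroblast markers, Rgs5 had 1.05 (SE 0.30; limma adjusted p = 0.147), and among the endothelial markers Lyve1 had -1.0 (SE 0.26; adjusted p = 0.104), with 0 of 16 and 0 of 18 genes past the threshold. At an unadjusted p under 0.05, 3 stellate markers were higher, and 2 endothelial markers were higher and 3 lower. Adjusted over each list alone, 2 stellate markers were higher and 3 endothelial markers lower. Rgs5 passed without Bgn knockout replicate 1 (limma adjusted p = 0.00372) and Lyve1 without wild type replicate 2 (0.0356).

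Of the 35 splits of the 8 arrays into 4 and 4, only the real 1 gave as many as 127 changed probes. The highest of the other splits gave 1. This argues against chance as the source of the count, as far as 35 splits can show. Every other split mixes the genotypes, which can lower its count. A difference in handling between the groups would give the same result as the genotype.

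Changed genes lay close to other changed genes: of 111 placed genes, 38 had another changed gene of a different family within 5 tested genes, against 13.9 on average and 35 at most in 10000 random sets (permutation p = 1e-04, the smallest they can give), which argues against random placement. Chromosome 4 held 29 changed genes against 6.78 expected (Fisher's exact test, adjusted p = 2.14e-10), among them Sytl1, Gpn2, Tesk1 and Cibar1. Chromosome 17 also passed, with 0 changed genes against 5.78 expected (Fisher's exact test, adjusted p = 0.0431). Just above the threshold (0.0557 to 0.0581) lay chromosomes 16 and 13 with more changed genes than expected, and 2 and 11 with fewer. Apcs, Cyp17a1, Zfp738, Rps3a1, Ppp1r3b, Trmt9b and Slc7a2, on chromosomes other than 4, were also among the 38. With Bgn itself not counted, 0 of the 38 lay on the X chromosome. This argues against a segment around Bgn carried with the targeted allele as the source of most of the 38. Such a segment is not excluded: of 29 measured neighbours of Bgn, 1 changed (3.45%), against 1.36% of the other genes (Fisher's exact test, p = 0.33). Sequence variants under probes stay open: 31 of the 38, and all 16 of them on chromosome 4, were lower, the direction that variants in the knockout mice would give. Of all 112 changed genes, however, 74 were lower. On chromosome 4 as a whole, 25 changed probes were lower and 6 higher, against 58 and 38 elsewhere (Fisher's exact test, p = 0.0506). The direction alone therefore cannot decide. Of the 38 genes, 11 had several tested probes. In 7 of these a second probe moved the same way at an unadjusted p under 0.05 in limma (exact binomial p = 0.0013). In Lsg1, Plekhf2, Galt and Gnl2 the second probe also had a value below 0, but a small one that missed this limit (-0.077, -0.11, -0.15 and -0.12). Without probe sequences, a variant shared by both probes cannot be told apart from a transcript change, nor can a variant for 27 genes with 1 tested probe. Segments of another strain's genome away from Bgn stay open: of 7 measured genes known to differ between inbred strains, 0 passed in limma (2 at an unadjusted p under 0.05 and also adjusted over the list alone, Alad with 0.49, which passed without Bgn knockout replicate 4 with 0.62, and Gbp2b with 0.89; camera adjusted p = 0.318), which excludes no segment elsewhere, and an effect of the genotype stays open as untested.

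Of 19 measured clock genes, 3 were lower and 1 was higher in the knockout, and 15 did not pass. Camera's call of the list did not hold with an estimated correlation (adjusted p = 0.768), nor did the list pass with fry (adjusted p = 0.0711). Genes that peak with Dbp (8 measured, 7 with values below 0) and genes that peak with Arntl (3 measured, 3 above 0) differed by 1.74 in mean log2 change. These sets hold the genes in which the pattern was seen, so the difference cannot support a different phase of the clock, which stays open. A variant under the Dbp probe alone would not lower other genes, and 5 others of its set were lower at an unadjusted p under 0.05 in limma. Of these, Tef and Nr1d1 passed the threshold. Such a variant therefore does not account for the falls of those genes. Whether it adds to the fall of Dbp itself, which has 1 tested probe, stays open. A different hour of collection in the groups cannot be told apart from an effect of the genotype on the clock, since 0 samples have an hour in their labels.

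Lower growth hormone signalling was a hypothesis from Cish (-3.15, which did not pass, limma adjusted p = 0.0814) and Bcl6 (2.21). Wild type replicate 1 lay towards the knockout arrays for both, with a log2 intensity of 8.49 for Cish and 10.49 for Bcl6. The other wild type arrays had 10.06 to 10.50 for Cish and 8.72 to 9.26 for Bcl6. Socs2 and Igf1, which like Cish are raised by growth hormone, had -0.94 (SE 0.64) and 0.081 (SE 0.098). On wild type replicate 1 Socs2 was 7.87 (other wild type arrays 9.85 to 10.29), while Igf1 lay within the range of the others. Their mean log2 change was -0.43 (SE 0.32, which takes the genes as independent although both were measured in the same livers). That mean neither meets a fall of both genes nor lies clearly above -0.2, so the hypothesis stays open.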
